A study of Mus musculus with 16 samples.

How the data were processed

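The series holds 16 one-colour Agilent arrays of primary alveolar type II cells of C57BL/6 mice, 4 in each group of normoxia (21% O2) and hyperoxia (85% O2) at 6 h and 24 h. Per the labels, total RNA was labelled with Cy3. The authors deposited 1 file per array from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), and per the file headers its processed signal is an intensity, background-subtracted and detrended within the array, with no normalization between arrays. The raw spot and background signals in the same files, also an intensity per the file headers, were used in 1 alternative. The series values that the authors deposited in a single table cover 43964 probes, 73 of them control probes. Its values are log2, with a median of 7.19 on every array and a correlation of 0.997 to 1.00 with the log2 processed signal of the same array. How the authors normalized that table is not stated, and quantile normalization is inferred from the values alone. It was used as an alternative only.

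Each array has 62976 spots, of which 59305 are not controls. No spot was saturated, and between 106 and 200 spots per array carried an outlier mark, which were left out where another spot of the probe remained. Spots of the same probe were averaged, 432 probes being on more than 1 spot, which left 55681 probes. Signals were taken as log2 and shifted so that the 75th percentile over non-control probes of each array was 0. Probes were named through the RefSeq accession in the array annotation (27428 probes), its symbol (3483) or an older symbol (507) matched to the mouse annotation of GRCm38.p6, used for names only. For 24263 probes the file's own name was kept, and 3295 printed names differ from the array's. Of 34781 gene names 22405 are RefSeq symbols. Each gene was represented by its brightest probe over all 16 arrays, and was tested if that probe was well above background on at least 3 of 4 arrays of a group. This left 25401 genes, 17294 of them with a RefSeq symbol. Of genes with more than 1 tested probe, 7465 in number, probes were called in opposite directions for 0 and 64 in the hyperoxia comparisons at 6 h and 24 h, 375 and 385 over time in normoxia and hyperoxia, and 3 in the difference. Named genes with disagreeing probes are marked in the text.

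Groups were compared in R 4.3.3 with limma 3.58.1: a linear model with 1 mean per group over all 16 arrays (12 residual and 2.23 prior degrees of freedom), contrasts, empirical Bayes moderation and two-sided tests, with Benjamini-Hochberg adjustment over the 25401 genes of each contrast and a threshold of 0.05. The contrasts were hyperoxia against normoxia at 6 h and at 24 h, 24 h against 6 h in normoxia and in hyperoxia, and the difference between the hyperoxia effects, 24 h less 6 h. A fold against a group with 0 of 4 arrays well above background is given as a lower bound, against the lowest signal that was well above background on each array, and none is given where neither group was. An array counted as well above background for a gene if any probe of the gene was. In all 33 gene lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Of the listed genes Gsta1, Trp53cor1, Hspa1b and Siglec5 have no probe under that name. The lists, contrasts, tests and the rule for named genes were fixed before the data were examined, from textbook knowledge. That rule took the 10 largest rises and falls per hyperoxia contrast, or 5 in the other contrasts, among genes with a symbol that passed and whose groups did not overlap (overlap was allowed in the difference), plus up to 4 called members with the largest change of each list that passed camera or, for hyperoxia, had at least 3 called members. Fewer than 4 were named where room was short: 2 per list at 24 h and over time in normoxia, and 1 in the other contrasts. For type II, NRF2, p53 and other-cell lists without a called member, the 2 brightest members are given as values. Members named beside counts of 5 or fewer that this rule does not take were chosen after their values were seen.

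All 6 h arrays stood on 1 slide and scan and all 24 h arrays on another, so time cannot be told apart from slide. On each slide normoxia took the first row and hyperoxia the second, so oxygen cannot be told apart from slide row, and the replicate number is the slide column. Residuals of same-numbered normoxia and hyperoxia arrays correlated at 0.25, 0.34, 0.24 and 0.26 at 24 h, all above the limit of 0.1 set for pairing, and each of the 8 arrays correlated best with its own number. At 6 h this held for 7 of 8 arrays. Replicate numbers were also used as a block, as planned over both slides and, after this was seen, within each slide. Between times, same-numbered arrays of the same oxygen group correlated at 0.004 to 0.084, below the limit of 0.1. Between 53.6% and 69.0% of probes of an array were well above background. The number of arrays limits the precision of every value. No 2 arrays were duplicates, the smallest SD of differences between arrays being 0.301.

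Alternatives were quantile normalization, median scaling, normexp background correction (offset 50), the authors' value table, no filter and a stricter filter (well above background on all 16 arrays), the mean of a gene's probes, a fit to only the arrays compared, trend and robust empirical Bayes, array weights, the replicate block, a minimum log2 fold change of 1, the estimated correlation and leaving out each array in turn. Chosen after seeing the data were the replicate block within a slide, leaving out the dimmest array, counting RefSeq symbols only, and the HIF list without members of other lists. Slide as a block was not run, since each slide holds 1 time. The 35 splits of 8 arrays into 4 and 4, or 100 draws for the difference and the correlation of effects, served to compare results with other groupings, and 10000 random lists matched on mean signal with list medians. The fit and camera steps were tested on simulated gene values with known changes, made from the spread of these arrays. Genes were independent of each other there, and the earlier steps were not tested. Tables were made with data.table (version 1.17.8), and figures with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Nothing deposited was left out apart from control spots, spots with outlier marks and dim genes. Results for a few genes that the rule names are not reported here, though these genes stay in all tests and counts of genes.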

Results

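RNA of primary alveolar type II cells, the surfactant-producing cells of the lung alveolus, from C57BL/6 mice was measured on 16 one-colour expression arrays. The cells had been kept in normoxia (21% O2) or hyperoxia (85% O2) for 6 h or 24 h, with 4 arrays in each of the 4 groups. Between 53.6% and 69.0% of the probes of an array were well above background, lowest on normoxia 24 h replicate 3. The arrays' 75th percentile of signal was 899 to 1021 at 6 h and 556 to 801 at 24 h. Values are log2 signal relative to each array's 75th percentile, 25401 genes were tested, and a gene rose or fell where its limma adjusted p was under 0.05. Errors of log2 fold changes are SE and those of group means are SD, with n = 4 arrays per group throughout. The largest rises and falls of a comparison are those of called genes with a gene symbol whose groups did not overlap. The first principal component held 48.3% of the variance and parted the times, with scores of 36.7 to 55.8 at 6 h and -63.7 to -31.6 at 24 h. The second held 16.3% and parted the oxygen groups at 24 h, with scores of 37.3 to 45.8 in normoxia and -35.9 to -30.6 in hyperoxia.

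After 6 h of hyperoxia a small set of genes was called, most of them higher. Chance is not excluded for their total, as given below. The largest rises among genes with detectable signal in both groups included Inka2, an inhibitor of the kinase PAK4, 3.53-fold higher (log2 fold change 1.82 ± 0.16, adjusted p = 9.87e-05). Targets of the transcription factor p53 stood beside it. The stress cytokine gene Gdf15 rose 2.33-fold (1.22 ± 0.14) and the receptor gene Eda2r 2.27-fold (1.18 ± 0.21). The cell cycle inhibitor Cdkn1a rose 2.16-fold (1.11 ± 0.14) and Mdm2, the ubiquitin ligase that degrades p53, 2.08-fold (1.05 ± 0.07, adjusted p = 6.26e-06). The mean of Mdm2 went from 4.90 ± 0.08 to 5.96 ± 0.11 and that of Cdkn1a from 3.62 ± 0.13 to 4.73 ± 0.33. Ddias, a gene induced by DNA damage, rose by 1.21 ± 0.13 and the thiamine transporter gene Slc19a2 by 1.26 ± 0.12 on the log2 scale. Kbtbd12 rose by 2.03 ± 0.37, but was well above background on 1 of 4 normoxia arrays. Mab21l3 (1.36 ± 0.18) and Gtse1, which encodes a G2 phase protein that binds p53 (1.02 ± 0.10), complete the 10 largest rises. Among the falls, the linker histone genes H1f5 and H1f1 changed by -1.01 ± 0.13 and -0.87 ± 0.09, and Mdm4, which encodes an inhibitor of p53, by -0.69 ± 0.09. The spindle gene Aspm (-0.70 ± 0.11), the checkpoint kinase gene Bub1b (-0.57 ± 0.10), Depdc1b (-0.70 ± 0.13), Arhgef39 (-0.77 ± 0.12) and the chromatin gene Atf7ip (-0.60 ± 0.08) also fell. Ms4a20 was at least 4.48-fold lower in hyperoxia, where it was well above background on 0 of 4 arrays.

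In all, 61 genes rose and 23 fell at 6 h of the 25401 tested, and 17 and 3 of these changed at least 2-fold. Every hyperoxia array lay on the same side of every normoxia array for all 84. Of all genes, 4.32% had groups without overlap, against 2.86% by chance. The highest adjusted p among the named genes was 0.0318, for Depdc1b. The calls of Btg2 and Depdc1b were lost in 6 of the 8 fits with 1 array left out, those of Bub1b and Eda2r in 5 and that of Kbtbd12 in 4. Aspm lost its call in 2 of these fits and Arhgef39 in 1, and the adjusted p reached 0.135 at most. Without normoxia replicate 4 the count was 33 higher and 11 lower, and without normoxia replicate 1 it was 37 higher. Without hyperoxia replicate 3 it was 132 higher and 61 lower, and without hyperoxia replicate 4 it was 13 lower. A fit to the 8 arrays of this time alone called 21 higher and 8 lower and ended the calls of Cdkn1a (adjusted p = 0.0588) and Mdm4 (0.108) among others. Without the filter the calls of Bub1b (adjusted p = 0.0546), Depdc1b (0.0601) and Kbtbd12 (0.0501) ended. Weighting the arrays by quality called 303 and 262.

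The p53 targets moved most as a group at 6 h: 16 of 32 measured members rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.52. It was the list that passed camera with both the preset correlation (adjusted p = 4.1e-45) and an estimated one (adjusted p = 0.000838 with an estimated correlation). Genes of mitosis shifted the other way, with a median of -0.35 over 30 members and camera adjusted p = 9.32e-22 (adjusted p = 0.155 with an estimated correlation). In other splits of the 6 h arrays, camera with the preset correlation gave some list a p as small as 4.24e-26. Its small p-values here thus do not exclude chance by themselves. Bub1b was the 1 mitosis gene that fell over all genes tested, while 17 fell adjusted over the list alone. NRF2 targets, the antioxidant and detoxifying genes, shifted up with a median of 0.23 over 33 members (camera adjusted p = 3.58e-11, and adjusted p = 0.0658 with an estimated correlation). None of them passed over all genes. The 4 that rose adjusted over the list alone were Gclc (0.45), Srxn1 (0.52), Txnrd1 (0.33) and Pgd (0.26), chosen after their values were seen. The 2 brightest NRF2 targets, the ferritin genes Fth1 and Ftl1, averaged 7.28 and 8.07 in normoxia and 7.38 and 8.14 in hyperoxia. HIF targets and glycolysis genes, commonly linked to low oxygen, also shifted up, with a median of 0.15 over 34 members (camera adjusted p = 8.72e-11, and adjusted p = 0.0658 with an estimated correlation). Of these, 1 rose over all genes, Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase (0.65 ± 0.09, 1.57-fold). Adjusted over the list alone 5 rose, the others being Bnip3 (0.94), Tpi1 (0.33), Pgam1 (0.25) and Pgk1 (0.31), chosen after their values were seen.

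Other lists passed camera at 6 h with the preset correlation alone. Immediate-early genes had a median of 0.09 over 24 members, with Btg2, a p53 target also, the 1 that rose (0.64 ± 0.11), at camera adjusted p = 0.00865 (adjusted p = 0.0658 with an estimated correlation). The list of a transitional alveolar epithelial state had 3 of 26 members higher, Gdf15, Cdkn1a and Mdm2, all of them in the p53 list too. It had a median of 0.04 and camera adjusted p = 0.000412 (adjusted p = 0.275 with an estimated correlation). ER chaperones and unfolded protein response genes (median -0.11 over 24 members), interferon-stimulated genes (-0.15 over 30), cytosolic heat shock genes (-0.07 over 19), ribosome biogenesis genes (-0.04 over 24) and integrated stress response genes (-0.11 over 28) shifted down. Their camera adjusted p was 2.52e-05, 0.000252, 0.00297, 0.0195 and 0.0277, and with an estimated correlation the adjusted p was 0.186, 0.186, 0.155, 0.299 and 0.822. No member of these 5 lists passed over all genes. Adjusted over the list alone the heat shock genes Hsph1 (-0.42) and Ahsa1 (-0.20) fell and the stress response gene Sesn2 (0.28) rose, chosen after their values were seen. The shift of the immediate-early list ended without normoxia replicate 1 (adjusted p = 0.0522) or hyperoxia replicate 3 (0.17). That of the integrated stress response ended without normoxia replicate 1 (0.525), hyperoxia replicate 3 (0.304) or hyperoxia replicate 4 (0.101). The ribosome list's ended without normoxia replicate 2 (0.129) or 4 (0.0707) or hyperoxia replicate 1 (0.0565) or 2 (0.0585). The transitional list's ended without hyperoxia replicate 3 (0.203).

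Surfactant and identity genes of type II cells had 0 of 27 members called at 6 h. The 2 brightest, Elovl1 and Ctsh, averaged 6.01 and 5.67 in normoxia against 5.98 and 5.86 in hyperoxia. No member was called either in the other lists: type I cell markers, AhR targets and xenobiotic enzymes, alveolar ion and fluid transport, autophagy and lysosome, cholesterol synthesis, circadian clock, DNA replication and G1/S, epithelial junctions, extracellular matrix, fatty acid and phospholipid synthesis, inflammatory cytokines and NF-kB targets, other antioxidant enzymes, respiratory chain subunits and TGF-beta targets. With the type II list and the marker lists of other cell types, these had camera adjusted p of 0.164 to 0.982. With a block on pairs of same-numbered arrays the type I, type II, inflammatory and macrophage lists passed, as given below. Adjusted over the list alone, 1 of 18 ion and fluid transport genes rose, and of the circadian genes Nr1d1 (0.65) rose and Nfil3 (-0.29) fell, chosen after their values were seen. The sign of median, mean and test differed for epithelial junctions, DNA replication, other antioxidant enzymes, ciliated cells, respiratory chain, extracellular matrix and TGF-beta targets. Among markers of other cell types, the smooth muscle gene Tagln averaged 8.21 and 8.23 in normoxia and hyperoxia and the collagen gene Col1a2 7.97 and 7.84. The neutrophil receptor gene Csf3r averaged 5.67 and 5.62, and Elane 2.46 and 2.65. Scgb1a1, the club cell secretory protein gene, averaged 4.99 and 5.13, and Pigr 2.43 and 2.37. Endothelial Kdr averaged 3.68 and 3.71 and Egfl7 1.21 and 1.16. The ciliated cell genes Foxj1 and Dnaic1 averaged 0.33 and -0.52 in normoxia against 0.34 and -0.46. For the macrophage genes Itgam and Cd14 the means were 4.33 and 2.21 against 4.53 and 2.22, with probes of Itgam that disagreed. For the lymphocyte genes Cd4 and Nkg7 they were 3.31 and 1.23 against 3.52 and 1.33. Without hyperoxia replicate 3 the change of Cd4 passed, at adjusted p = 0.0496. Tagln and Col1a2 were thus brighter than Elovl1 and Ctsh, though signals of different probes do not measure cell shares. The share of other cells in the samples is not known, so changes cannot be assigned to type II cells alone.

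After 24 h of hyperoxia the response was broad: 3942 genes rose and 3251 fell, 668 and 517 of them at least 2-fold. Most of the 10 largest falls without overlap between the groups were of genes of cell division. The mitotic kinesin genes Kif11 (10.5-fold lower, log2 fold change -3.39 ± 0.23) and Kif2c (-3.18 ± 0.20) fell, as did the proliferation marker Mki67 (8.9-fold lower, -3.15 ± 0.16), the mitotic kinase gene Plk1 (-3.15 ± 0.13) and the spindle gene Ska1 (-3.19 ± 0.12). The others of the 10 were Fbxo5, for an inhibitor of the anaphase-promoting complex (-3.12 ± 0.13), Aunip (-3.21 ± 0.20), Depdc1b (-3.35 ± 0.13), the histone gene H1f5 (10.4-fold lower, -3.38 ± 0.13) and the cyclin gene Ccne2 (-3.07 ± 0.39, well above background on 1 of 4 hyperoxia arrays). The mean of Mki67 went from 3.80 ± 0.31 to 0.64 ± 0.28 and that of Kif11 from -0.62 ± 0.44 to -4.01 ± 0.39. All 30 measured genes of mitosis and G2/M fell, with a median of -2.28 (camera adjusted p = 1.57e-41, and 0.0224 with an estimated correlation). All 30 fell adjusted over the list alone too. Of 30 genes of DNA replication and G1/S, 28 fell, such as the replication licensing gene Cdc6 (5.61-fold lower, -2.49 ± 0.11). The other two, Slbp (-0.18) and Ung (-0.35), were among the 30 that fell adjusted over the list alone. Their median was -1.31 (camera adjusted p = 2.13e-31, and 0.00756 with an estimated correlation).

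The p53 targets rose further at 24 h, 28 of 32 measured members with a median of 1.46 and 0 lower over all genes (camera adjusted p = 7.2e-23, and 0.00756 with an estimated correlation). Ddit4l, which encodes an inhibitor of mTOR signalling, rose 5.41-fold (2.44 ± 0.13), Trp53inp1 4.65-fold (2.22 ± 0.14), Mdm2 3.77-fold (1.91 ± 0.07) and Cdkn1a 3.57-fold (1.84 ± 0.14). The members outside this count were Ddit4 (0.10), Plk3 (-0.24), Rrm2b (-0.19) and Sesn1 (-0.04). Adjusted over the list alone 28 rose and 1, Plk3, fell. Inka2 rose 8.53-fold (3.09 ± 0.16). Others among the 10 largest rises were the axon guidance receptor gene Robo3 (3.47 ± 0.18) and the carboxylesterase gene Ces2e (14.3-fold, 3.84 ± 0.37). A further 4 of them were well above background on 0 of 4 normoxia arrays: Svop rose at least 9.55-fold, Rimbp3 at least 3.93-fold, the Wnt receptor gene Fzd10 at least 3.88-fold and the homeobox gene Hoxc13 at least 2.79-fold. The adjusted p of the 20 largest changes lay between 5.26e-10, for Ska1, and 3.12e-05, for Ccne2.

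**Figure D1:**
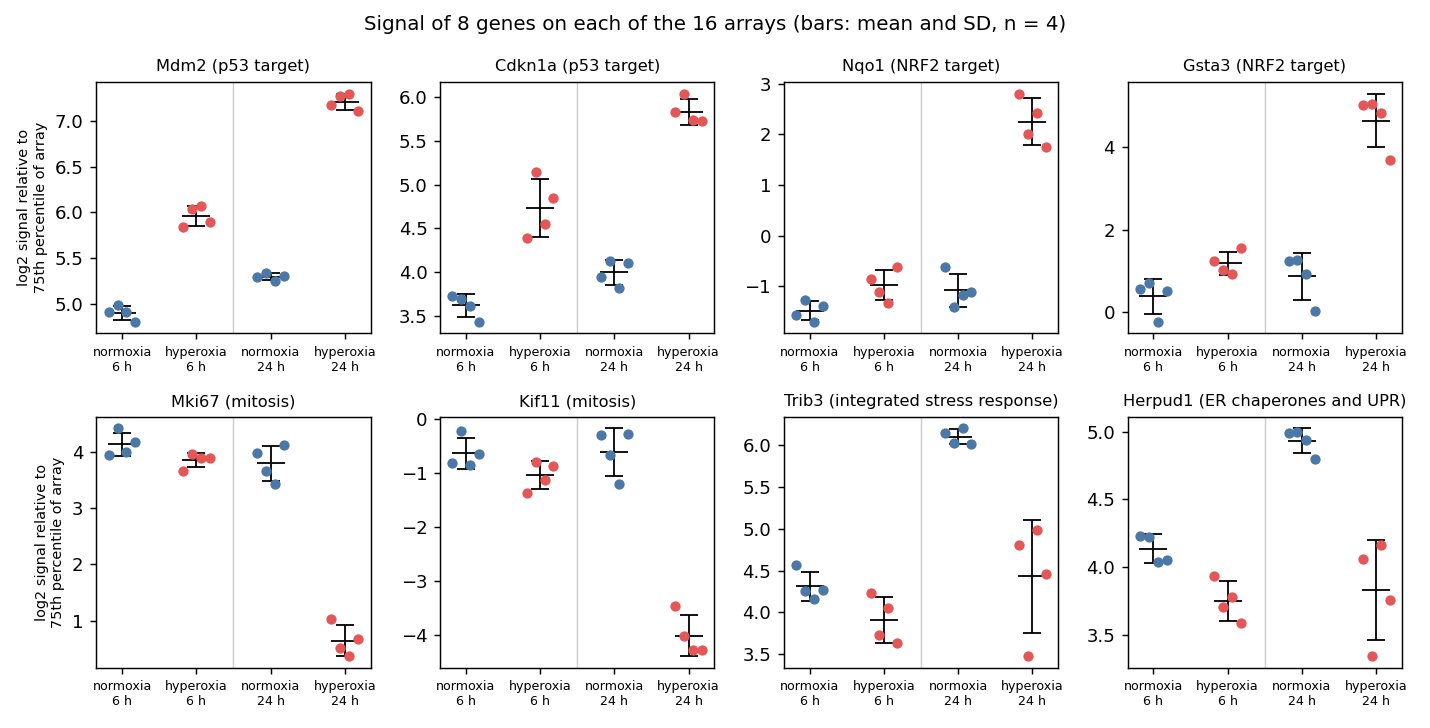
Signal of 8 genes on each of the 16 arrays, as log2 signal relative to the 75th percentile of the array, with points for arrays and bars for the mean and SD (n = 4 per group). Mdm2 and Cdkn1a are higher in hyperoxia at 6 h and 24 h. At 24 h Nqo1 and Gsta3 are higher and Mki67, Kif11, Trib3 and Herpud1 lower in hyperoxia than in normoxia.

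Most NRF2 targets rose at 24 h. The NRF2 target Gsta3, a glutathione transferase gene, was 13.6-fold higher (3.77 ± 0.33). Nqo1, which encodes a quinone reductase, rose by 3.33 ± 0.22 on the log2 scale, and Gsta4 was 9.03-fold higher (3.18 ± 0.23). Probes of the closely related Gsta genes may not tell their transcripts apart, so which of them rose is uncertain. The mean of Nqo1 went from -1.08 ± 0.33 to 2.25 ± 0.46. In all 23 of 33 NRF2 targets rose and 1 fell, Slc7a11 (-0.69), with a median of 0.75 (camera adjusted p = 6.3e-14, and 0.0224 with an estimated correlation). The counts adjusted over the list alone were 23 and 1 too. Of the AhR targets and xenobiotic enzymes 5 of 12 rose (6 adjusted over the list alone): Nqo1, the AhR repressor gene Ahrr (1.37 ± 0.20), Fmo2 (1.27), Cyp1b1 (0.61) and Tiparp (0.47). That list had a median of 0.32 and camera adjusted p = 0.0341, lost with an estimated correlation (adjusted p = 0.315 with an estimated correlation) and without hyperoxia replicate 2 (0.0757). Among other antioxidant enzymes 7 of 27 rose, including Sod3, for extracellular superoxide dismutase (1.00 ± 0.31), and Gpx1, for a glutathione peroxidase (0.50 ± 0.06). Msrb2 (-0.45), Selenok (-0.36) and Gpx7 (-0.34) fell, and the list as a whole did not pass camera (adjusted p = 0.933; median -0.07 with a mean and a test above 0).

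Stress response and biosynthetic genes were lower in hyperoxia at 24 h. Of 28 integrated stress response genes 20 fell and 1 rose, Sesn2 (0.31), with a median of -0.80, and 21 fell and 1 rose adjusted over the list alone. Here fell means lower than in normoxia at 24 h. Most of these genes were higher at 24 h than at 6 h in both oxygen groups, though time goes with slide, as given below. Pck2, for mitochondrial PEP carboxykinase, was 3.42-fold lower (-1.77 ± 0.15) and the pseudokinase gene Trib3 3.17-fold lower (6.09 ± 0.09 in normoxia, 4.43 ± 0.67 in hyperoxia). The list had camera adjusted p = 2.34e-10 (adjusted p = 0.225 with an estimated correlation). ER chaperones and unfolded protein response genes fell in 20 of 24 cases over all genes and adjusted over the list alone, with a median of -0.61 (camera adjusted p = 6.11e-12, and 0.0224 with an estimated correlation). Examples are the ER-associated degradation genes Derl3 (-1.38 ± 0.19) and Herpud1 (-1.10 ± 0.14). The members outside the count were Atf6 (-0.16), Canx (0.14), Pdia3 (-0.07) and Syvn1 (-0.12). Cholesterol synthesis genes fell in 22 of 25 cases, also adjusted over the list alone, with a median of -0.57 and camera adjusted p = 1.26e-11 (adjusted p = 0.0564 with an estimated correlation). The sterol sensor gene Insig1 changed by -1.10 ± 0.13 and the farnesyl diphosphate synthase gene Fdps by -0.92 ± 0.07. Hsd17b7 (-0.03) and Srebf2 (-0.08) were among those that did not pass. Fatty acid and phospholipid synthesis genes fell in 12 of 25 cases (13 adjusted over the list alone), such as the elongase gene Elovl6 (-0.90 ± 0.10), with a median of -0.28 and camera adjusted p = 0.000215 (adjusted p = 0.0702 with an estimated correlation). The 2 that rose were the phosphatidate phosphatase gene Lpin1 (0.93 ± 0.19) and Agpat2 (0.25). Ribosome biogenesis genes fell in 18 of 24 cases (20 adjusted over the list alone), among them Pes1 (-1.03 ± 0.09) and Dkc1 (-0.81 ± 0.06), with a median of -0.34 (camera adjusted p = 2.7e-10, and 0.00756 with an estimated correlation). Immediate-early genes rose in 13 of 24 cases (14 adjusted over the list alone), led by the phosphatase gene Dusp1 (2.82-fold) and Btg2 (2.81-fold, 1.49 ± 0.11). Klf4 (-0.76) and Myc (-0.37) fell. Their median was 0.43 (camera adjusted p = 9.01e-05, and 0.00756 with an estimated correlation).

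**Figure D2:**
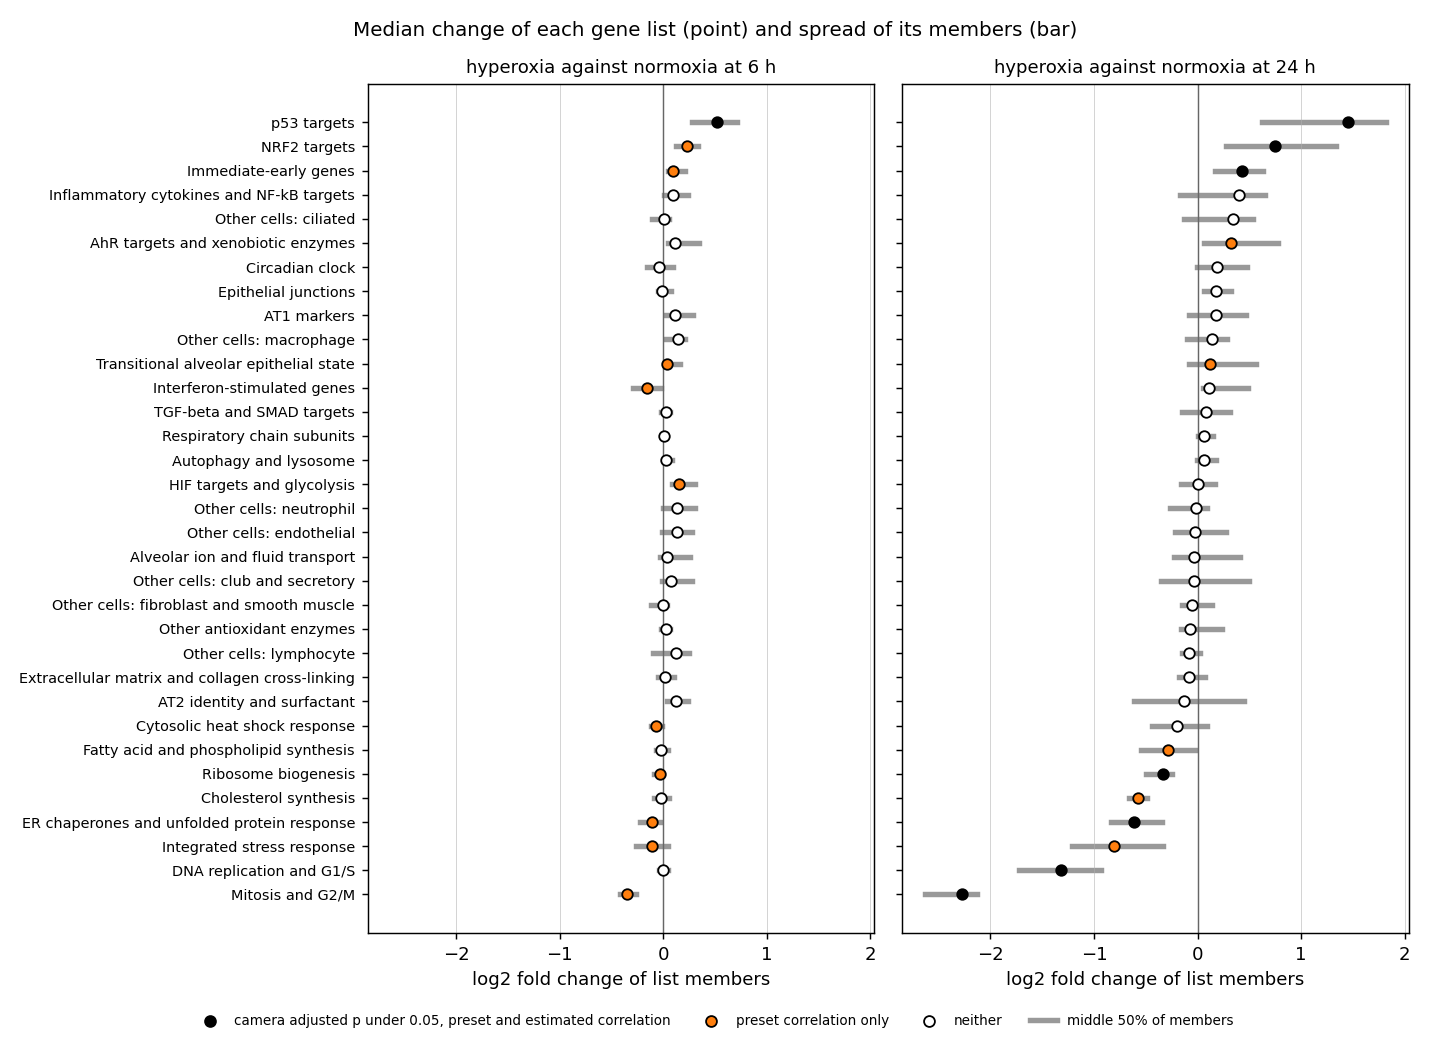
Median log2 fold change of each of the 33 gene lists in hyperoxia against normoxia at 6 h and at 24 h, with bars for the middle 50% of members; fill shows whether the list passed camera with the preset and the estimated correlation, the preset one alone, or neither. At 24 h mitosis lies lowest, at -2.28, and p53 targets highest, at 1.46.

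Genes of type II cell identity went both ways at 24 h: 7 of 27 fell and 3 rose (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0867. Lamp3, a lamellar body membrane gene, fell (-1.03 ± 0.08), as did the surfactant protein gene Sftpb (-0.95), Etv5 (-0.79), Fasn (-0.74), Muc1 (-0.68), Fabp5 (-0.55) and Lpcat1 (-0.28). Abca3, the lamellar body lipid transporter gene, rose (0.68), as did Ctsh (0.44) and Cxcl15, which was not well above background on any array of either group. Of the type I cell markers 4 of 25 rose, Gprc5a (0.72 ± 0.17), Spock2 (0.70 ± 0.16), Pmp22 (0.65) and S100a6 (0.22). The 2 that fell were Emp2 (-0.45) and Sema3e (-0.34), with camera adjusted p = 0.325. The transitional state list had 8 of 26 members higher, Mdm2 and Cdkn1a with the largest changes, and a median of 0.12. Its camera adjusted p was 0.0451, lost with an estimated correlation (adjusted p = 0.604 with an estimated correlation), with replicate numbers as a block (0.0609) and without normoxia replicate 1 (0.142) or hyperoxia replicate 2 (0.0757). Ion and fluid transport genes were 5 higher and 2 lower of 18 (5 and 3 adjusted over the list alone; camera adjusted p = 0.626). Kcnj15 (1.23), Atp1b1 (0.57), Sgk1 (0.43) and Clcn2 (0.36) were among those that rose. The water channel gene Aqp1 (-1.37 ± 0.12) and Slc26a9 (-0.88) fell. Junction genes had 2 of 23 higher, Cldn3 (1.11) and Cldn4 (0.66), 1 of them adjusted over the list alone, with camera adjusted p = 0.133. Blocking on pairs of same-numbered arrays gave 0.00909 for the junction list and for the inflammatory list, which without the block had adjusted p = 0.824 and 0.51 with an estimated correlation.

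Among inflammatory genes 7 of 28 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.13). The neutrophil chemokine gene Cxcl5 was higher (1.60 ± 0.48), as was the granulocyte growth factor gene Csf3 (1.32 ± 0.37). Lcn2 (-1.30), Nfkb2 (-0.35) and Relb (-0.24) were lower. Interferon-stimulated genes had 6 of 30 higher, including Ifit1 (1.03 ± 0.29) and Mx2, at least 2.14-fold, and Oasl1 lower (-0.61; camera adjusted p = 0.146). Of 19 cytosolic heat shock genes 9 fell, such as the cochaperone gene Fkbp4 (-0.75 ± 0.10). Hspa1a (1.33 ± 0.10, a probe that near-identical Hspa1b may share) and Hspa4l (0.58) rose (camera adjusted p = 0.0998). Circadian genes were 6 higher and 3 lower of 19 (camera adjusted p = 0.236). Dbp (1.49 ± 0.14) and Nr1d1 (1.41 ± 0.16) rose and Ciart (-0.78), Nfil3 (-0.58) and Cry2 (-0.42) fell. HIF targets and glycolysis genes went both ways, with 6 of 34 higher, including the vasodilator peptide gene Adm (1.78 ± 0.31) and Ankrd37 (0.99 ± 0.20). The 5 lower ones were P4ha1 (-0.77), P4ha2 (-0.60), Pfkl (-0.52), Slc16a3 (-0.34) and Mif (-0.20). Their camera adjusted p was 0.933. Autophagy and lysosome genes were 7 higher and 2 lower of 30 (camera adjusted p = 0.245). Atp6v1a (0.53 ± 0.08) and Gabarapl2 (0.45 ± 0.13) rose and Hexa (-0.45) and Gla (-0.44) fell. Respiratory chain genes were 8 higher, including Ndufa4 (0.26 ± 0.09) and Ndufa10 (0.24 ± 0.06), and 1 lower, Cycs (-0.22), of 36 (camera adjusted p = 0.141). Adjusted over the list alone 6 were higher and 1 lower. Matrix genes were 1 higher, Lox (0.42), and 3 lower, Tgm2 (-1.03 ± 0.19), Loxl1 (-0.46 ± 0.15) and Spp1 (-0.42), of 35 (camera adjusted p = 0.255). Of these, 1 was higher and 2 were lower adjusted over the list alone. TGF-beta targets were 5 higher, Id1 (0.67 ± 0.12), Tgfb3 (0.49), Smad7 (0.39), Ski (0.39) and Skil (0.37), and 1 lower, Snai2 (-0.64 ± 0.19), of 27 (camera adjusted p = 0.431). Unless given, counts adjusted over the list alone were the same in the lists of this paragraph.

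Markers of other cell types did not move together at 24 h. Ciliated cell genes were 5 higher, Tekt1 (1.04 ± 0.32), Rfx3 (0.79), Rfx2 (0.75), Ccdc40 (0.49) and Tppp3 (0.46), and 1 lower, Mlf1 (-1.30 ± 0.13), of 14 (camera adjusted p = 0.289). They had a list median of 0.34, the farthest from 0 of the 7 marker lists. Fibroblast and smooth muscle genes were 2 higher, the growth factor gene Fgf10 (1.49 ± 0.26) and Tcf21 (0.87), and 3 lower, Des (-1.62 ± 0.23), Thy1 (-0.53) and Cnn1 (-0.45), of 21 (0.598). Club cell genes were 1 higher, Scgb1a1 (0.78 ± 0.25), and 2 lower, Cckar (-2.15 ± 0.33, well above background on 1 of 4 hyperoxia arrays) and Bpifb1 (-0.22), of 14 (0.604). Endothelial genes were 1 higher, Tmem100 (1.67), and 1 lower, Egfl7 (-0.31), of 15 (0.978). Neutrophil genes were 1 higher, S100a8 (1.75), and 1 lower, Lcn2 (-1.30), of 12 (0.751), and macrophage genes 1 higher, Cd68 (1.02), of 19 (0.604). None of 14 lymphocyte genes was called (0.604). Cd4, with probes that disagreed, averaged 3.24 in normoxia and 3.26 in hyperoxia and Nkg7 1.73 and 1.67. The counts of these 7 lists were the same adjusted over the list alone. Median, mean and test differed in sign for the fibroblast, ion transport, other antioxidant and endothelial lists.

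Of the 7193 genes called at 24 h, 6422 had no overlap between the groups. Of all genes 33.2% had none, against 2.86% by chance. Replicate numbers paired the arrays of this time, and with them as a block within the slide 4718 genes rose and 3761 fell. Among the named genes, the call of Ndufa4 was lost in 7 of the 8 fits with 1 array left out, that of Scgb1a1 in 6 and that of Loxl1 in 5. Sod3 lost its call in 4 of these fits, Cxcl5 and Tekt1 in 3, and Csf3, Gabarapl2 and Snai2 in 1. The adjusted p reached 0.134 at most. Background correction by normexp ended those of Spock2, Cxcl15, Cxcl5, Csf3 and Tekt1. The replicate block over both slides ended that of Ndufa4 (limma adjusted p = 0.0624).

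The hyperoxia effects at the 2 times were compared gene by gene. Of the 61 genes higher at 6 h, 54 were also higher at 24 h, where independent lists would share 9.47. Of the 23 lower at 6 h 20 were lower at 24 h, where independent lists would share 2.94. No gene went from higher to lower and 1 went from lower to higher. Across the 25401 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.314 (jackknife SE 0.0973) and Spearman rho = 0.272. Over the 84 genes called at 6 h r was 0.625, and 69 of them had a larger change in the same direction at 24 h. The 2 comparisons share each gene's estimate of spread, which can raise the overlap above that of independent lists. Oxygen also goes with slide row at both times, so a row bias could raise the overlap and the correlation.

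**Figure D3:**
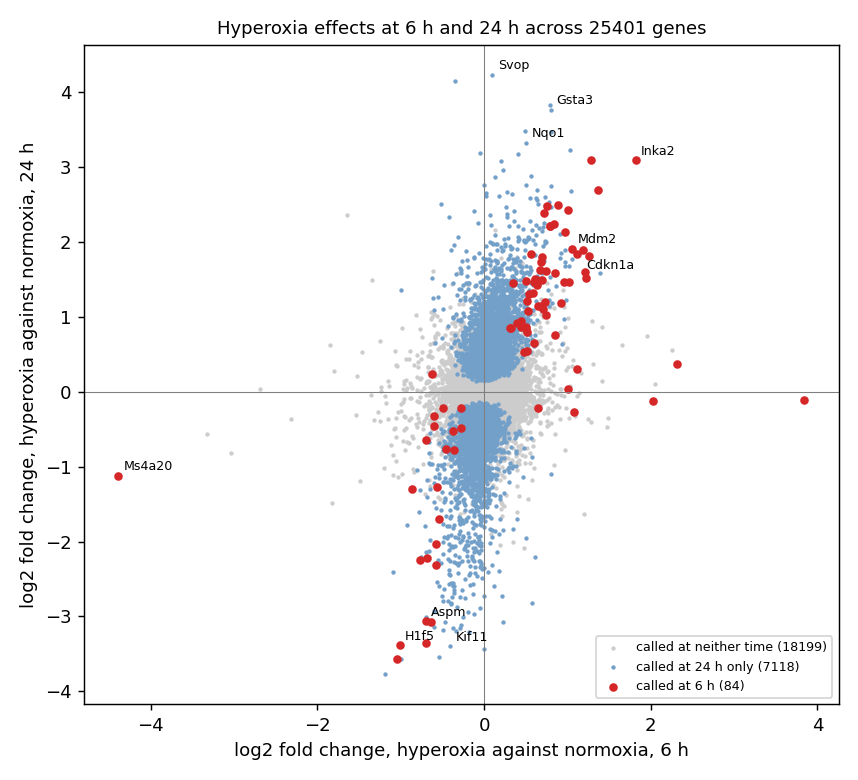
Log2 fold change of each gene in hyperoxia against normoxia at 6 h (horizontal) and 24 h (vertical), with 84 genes called at 6 h in red, 7118 called at 24 h and not at 6 h in blue, and 18199 called at neither time in grey. Nearly all red points lie in the lower left or upper right, and Mdm2, Inka2, H1f5 and Aspm are further from 0 at 24 h.

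The test of the difference between the effects, 24 h less 6 h, called 1683 genes with a more positive effect at 24 h and 1432 with a more negative one, and 61 of the 84 genes called at 6 h were among them. The mitosis list differed most, with a median of -1.99. Kif11 (-2.99 ± 0.33), Mki67 (-2.87 ± 0.23), Aunip (-3.03 ± 0.29) and Ccne2 (-3.30 ± 0.55) lay among the most negative, as did Tm6sf1 (-2.95 ± 0.62). DNA replication genes had a median of -1.30. The p53 targets were more positive at 24 h (median 0.77, 21 of 32 members called), such as Dcxr, for a xylulose reductase (1.51 ± 0.18), and NRF2 targets likewise (0.58, 18 of 33), such as Gsta3 (2.97 ± 0.46). ER genes (-0.44, Derl3 -1.24 ± 0.27), ribosome biogenesis genes (-0.26, Pes1 -0.80 ± 0.13) and immediate-early genes (0.26, Dusp1 1.29 ± 0.24) also differed. These 7 lists passed camera with the preset correlation and with an estimated one, at adjusted p between 0.00888 and 0.0457 with an estimated correlation. With the preset correlation alone cholesterol synthesis (-0.52, Insig1 -1.19 ± 0.19), integrated stress response (-0.74, Pck2 -1.41 ± 0.22), fatty acid synthesis (-0.31, Elovl6 -0.84 ± 0.14), type II identity (-0.31, Sftpb -1.26 ± 0.35), interferon-stimulated (0.29, Ifit3 1.06 ± 0.26) and HIF target genes (-0.16, Pfkl -0.95 ± 0.23) passed. With an estimated correlation their adjusted p was 0.0582, 0.236, 0.0731, 0.522, 0.253 and 0.539. The largest positive differences were those of Svop (4.14 ± 0.30), Ms4a20 (3.27 ± 0.81), Rimbp3 (3.25 ± 0.54), Ces2e (3.05 ± 0.52) and Hoxc9 (3.03 ± 0.38). Of these, Svop, Ms4a20, Rimbp3 and Hoxc9 were well above background on 0 of 4 arrays of at least 1 group, as was Tm6sf1, so the sizes of their differences are uncertain. The adjusted p over all 21 named genes was at most 0.0298, for Sftpb. Without hyperoxia 6 h replicate 3 the counts were 2707 and 2265 and with array weights 3137 and 2603. The HIF list no longer passed under quantile normalization (0.0737), normexp (0.144) or the authors' values (0.0736). The Sftpb call was lost in 6 of the 16 fits with 1 array left out, at adjusted p up to 0.0642.

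Cells kept for 24 h differed from those kept for 6 h in normoxia and in hyperoxia, but all 6 h arrays were on 1 slide and all 24 h arrays on another, so time and slide cannot be told apart. In normoxia, the surfactant protein genes Sftpa1 (-2.91 ± 0.34, well above background on 2 of 4 arrays at 24 h) and Sftpd (-2.81 ± 0.30) were lower at 24 h. The claudin gene Cldn3 (-1.82 ± 0.27), Ocln (-1.77 ± 0.23), the chloride transporter gene Slc26a9 (-2.44 ± 0.27) and the sodium channel gene Scnn1a (-1.67 ± 0.39) fell too. Of the type II identity genes 15 of 27 fell and 4 rose, Etv5, Cebpa, Soat1 and Elovl1 (median -0.55). Of the junction genes 16 of 23 fell and Pkp3 rose (list median -1.14), and of the ion transport genes 10 of 18 fell and 1 rose. These 3 lists passed camera with the preset correlation, but their adjusted p was 0.359, 0.299 and 0.205 with an estimated correlation. Of the type I cell markers 9 of 25 fell and 5 rose (camera adjusted p = 0.293). Markers of airway cells fell with them: Scgb1a1 by 5.66 on the log2 scale (4.99 ± 0.53 to -0.68 ± 0.23), Scgb3a1 at least 10.1-fold, Tekt1 (-2.35 ± 0.32) and Fam183b at least 1.90-fold. Of 14 ciliated cell genes 11 fell (median -0.95, and -0.71 with undetected genes at their bound). Of 14 tested members of the club and secretory cell list 9 fell and 2 rose, Pigr and Trp63 (list median -0.82, and -0.70 at the bound). The chemokine genes Ppbp (-4.71 ± 0.51) and Cxcl5 (-4.18 ± 0.48) and Csf3 (-2.97 ± 0.37) fell, with 16 of 28 inflammatory genes, and Lcn2, Tnfaip2 and Csf1 rose. Stress and matrix genes were higher: 27 of 28 integrated stress response genes rose (median 1.12), led by Ddit3 (2.61 ± 0.22) and the glycine transporter gene Slc6a9 (1.92 ± 0.18), and Atf3 fell. Of 35 matrix genes 27 rose, such as the gelatinase genes Mmp2 (1.49 ± 0.28) and Mmp9 (1.47 ± 0.19), while the laminin gene Lama3 was among those that fell (list median 0.61). Fibroblast and smooth muscle markers, 6 of which stand in another list too, rose in 12 of 21 cases, such as Des (1.46 ± 0.23), while Fgf10 (-1.36 ± 0.26) and Inmt fell (list median 0.52). HIF targets rose in 22 of 34 cases, including P4ha1 (0.92 ± 0.11) and Ero1a (0.91 ± 0.13), and Car9 fell. Autophagy genes such as Hexa (0.77 ± 0.12) and Sqstm1 (0.75 ± 0.16) rose in 22 of 30 and Gabarapl2 and Atg5 fell. Mitosis genes such as Nusap1 (-0.82 ± 0.18) and Ccnf (-0.73 ± 0.11) fell in 23 of 30 and replication genes such as Cdc6 (-0.85 ± 0.11) and Mcm5 (-0.68 ± 0.11) in 21 of 30. The members named here without a value, and Sftpc, the surfactant protein C gene (-2.50 ± 0.43), were chosen after their values were seen.

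Over time in normoxia 5246 genes rose and 5975 fell. The largest rises were those of Car6 (3.95 ± 0.39), Kcnma1 (2.96 ± 0.59) and, from undetected at 6 h, Gm19410 at least 5.88-fold, Tm6sf1 at least 4.94-fold and the mast cell protease gene Mcpt2 at least 2.73-fold. Gm4610 (-3.90 ± 0.71, well above background on 1 of 4 arrays at 24 h) was among the largest falls with genes named above. Of the 33 lists 19 passed camera with the preset correlation and none with an estimated one, at adjusted p of 0.122 to 0.76 with an estimated correlation. Besides those above, the immediate-early list fell (8 of 24 lower, such as Ier3 at -1.31 ± 0.13, with Klf4 at 2.06 ± 0.17 and Klf2 higher). Circadian genes (Ciart 1.59 ± 0.17), p53 targets (Pvt1 0.91 ± 0.11, Perp -0.91 ± 0.19), ribosome biogenesis (Gnl3 0.44 ± 0.07, Rrp9 0.37 ± 0.12), respiratory chain (Uqcrq 0.62 ± 0.09) and fatty acid synthesis genes (Chka 0.65 ± 0.08, Gpam 0.62 ± 0.09) passed upward, but each lost this under some other scaling, as did the fibroblast and club cell lists. The respiratory chain and fatty acid lists turned downward under at least 1 of them. Scaling to the median instead moved the median gene from -0.02 to 0.19 and gave 10103 higher and 3410 lower genes. Normexp moved it to 0.10 and gave 8465 and 3649, so directions here are relative to each array's 75th percentile. Normexp ended the calls of Fgf10 (-0.24, adjusted p = 0.134) and Fam183b (-0.40, adjusted p = 0.144), and that of Rrp9 ended under quantile normalization (0.0552), normexp (0.0866) and the authors' values (0.0552).

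In hyperoxia 6350 genes rose and 6950 fell between 6 h and 24 h. Falls again included Scgb1a1 (-5.02 ± 0.25), Ppbp (-3.85 ± 0.51), Scgb3a1 (-3.78 ± 0.70) and Gm4610, at least 9.52-fold, and also Mx1, an interferon-induced gene (-3.75 ± 0.51, well above background on 1 of 4 arrays at 24 h). The largest rises were those of trypsin genes Try4 (4.05 ± 0.46) and Try5 (3.99 ± 0.42), whose near-identical sequences a probe may not part, Svop (3.89 ± 0.21, well above background on 2 of 4 arrays at 6 h), the mast cell protease gene Mcpt1 (3.66 ± 0.40) and the carboxypeptidase gene Cpa6, at least 3.07-fold. All 30 mitosis genes fell (median -2.45, Kif2c -3.39 ± 0.20), as did all 30 replication genes (-1.83, Ccne2 -3.72 ± 0.39). So did 21 of 25 cholesterol synthesis genes (-0.60, Idi1 -1.14 ± 0.12) and 17 of 24 ER genes (Derl3 -2.09 ± 0.19), while Atf6 rose. Also lower were 18 of 27 type II identity genes (-0.95, Sftpb -2.72 ± 0.25), 16 of 23 junction genes (-0.75, Cldn18 -2.50 ± 0.44) and 15 of 28 inflammatory genes (Cxcl5 -3.03 ± 0.48). Marker genes of club cells (9 of 14, Scgb1a1 the lowest) and ciliated cells (9 of 14, Fam183b at least 2.11-fold) fell too, though normexp ended the call of Fam183b (-0.24, adjusted p = 0.382). Rises took in 29 of 32 p53 targets (median 0.84, Eda2r 1.61 ± 0.21), 24 of 33 NRF2 targets (0.66, Gsta3 3.45 ± 0.33) and 24 of 30 autophagy genes (Atp6v1a 0.88 ± 0.08). They also took in 24 of 35 matrix genes (0.53, Mmp2 1.55 ± 0.28), 18 of 28 integrated stress response genes (0.52, Ddit3 2.52 ± 0.22) and 12 of 19 circadian genes (Dbp 2.41 ± 0.14). In all 21 lists passed camera with the preset correlation and none with an estimated one, at adjusted p of 0.0591 to 0.541 with an estimated correlation. The HIF (median 0.21, Adm 1.34 ± 0.31), interferon (0.39, although Mx1 fell) and respiratory chain lists (0.17, Uqcrq 0.57 ± 0.09) passed upward. So did the fibroblast (0.47, Inmt -1.23 ± 0.20 against 12 of 21 higher) and TGF-beta lists (0.20, although Itgb6 lay at -1.83 ± 0.28). The ribosome list passed downward (-0.23, Dkc1 -0.69 ± 0.06). Each of these lists lost this under some other scaling. Scaling to the median moved the median gene from -0.02 to 0.20 and gave 10679 higher and 4204 lower genes. The p-values of all comparisons measure only the spread between these arrays, since the labels do not say whether the replicates were separate animals or cultures.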

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

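The tests of other-cell markers for the p53 and mitosis patterns at 24 h, of the HIF list without shared members, of all lists over the splits at 6 h and of draws that keep the pairs at 24 h were chosen after the results were seen.

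The hyperoxia effect differed between 6 h and 24 h by the test of the difference itself for 1683 genes with a more positive and 1432 with a more negative effect at 24 h, 3115 in all. Of 100 draws with oxygen labels regrouped within each time, the real one included, 4 gave as many, the highest other giving 4396. All 4 had the real grouping at 24 h, and no draw with another called more than 11. Of 100 draws that part the 4 pairs of arrays at 24 h, 13 gave as many (highest other 6148), again all with the real grouping at 24 h. The total thus follows the grouping at 24 h, and chance is not excluded for the part that rests on 6 h. The median differences of the lists that passed camera were -1.99 for mitosis, -1.30 for DNA replication, -0.74 for the integrated stress response, -0.52 for cholesterol synthesis, -0.44 for ER chaperones, -0.31 for type II identity and for fatty acid synthesis, -0.26 for ribosome biogenesis and -0.16 for HIF targets. They were 0.26 for immediate-early genes, 0.29 for interferon-stimulated genes, 0.58 for NRF2 targets and 0.77 for p53 targets. Among named genes the differences were -3.30 for Ccne2, -3.03 for Aunip, -2.99 for Kif11, -2.95 for Tm6sf1, -2.87 for Mki67, -1.41 for Pck2, -1.26 for Sftpb, -1.24 for Derl3, -1.19 for Insig1, -0.95 for Pfkl, -0.84 for Elovl6 and -0.80 for Pes1. On the positive side they were 1.06 for Ifit3, 1.29 for Dusp1, 1.51 for Dcxr, 2.97 for Gsta3, 3.03 for Hoxc9, 3.05 for Ces2e, 3.25 for Rimbp3, 3.27 for Ms4a20 and 4.14 for Svop.

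In 18 of 343 groups of 4 values of named genes 1 array stood far from the other 3, and chance alone would mark about 1 group in 20. In normoxia at 6 h these were Sftpd at 2.06 on replicate 1 (others 3.09 to 3.13), Uqcrq at 6.598 on replicate 1 (6.44 to 6.47) and Tagln at 8.11 on replicate 3 (8.23 to 8.24), while in hyperoxia at 6 h it was Cd4 at 3.07 on replicate 3 (3.61 to 3.69). In normoxia at 24 h they were Adm at -1.03 on replicate 2 (-0.24 to -0.08), Ndufa10 at 3.18 on replicate 1 (3.33 to 3.35), Mcm5 at 2.73 on replicate 3 (2.89 to 2.91), Nusap1 at -0.028 on replicate 3 (0.30 to 0.36) and Btg2 at 2.22 on replicate 4 (2.68 to 2.72). Replicate 4 also stood apart for Scgb1a1 at -0.34 (-0.82 to -0.76) and Slc6a9 at 5.30 (5.55 to 5.57). In hyperoxia at 24 h they were Cldn18 at -0.50 on replicate 2 (-2.58 to -2.30), Derl3 at -4.43 on replicate 2 (-4.84 to -4.78) and Tekt1 at -3.02 on replicate 2 (-4.00 to -3.84). Others there were Gm4610 at -7.52 on replicate 3 (-6.50 to -6.46), Gsta3 at 3.68 on replicate 4 (4.82 to 5.05), Lamp3 at 3.18 on replicate 4 (3.33 to 3.36) and Nr1d1 at 0.61 on replicate 4 (0.26 to 0.30).

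Whether other groupings of the same arrays would call as much was counted for each comparison. At 6 h 3 of the 35 splits called as many genes as the real one, 84 against a highest other of 555. Chance is thus not excluded for that total. Of the 8 splits there that part all 4 same-numbered pairs the highest other called 0. These were not taken as the reference, since 1 same-number correlation at 6 h, 0.086, is under the limit of 0.1. The split that called 555 sets normoxia replicate 1 and hyperoxia replicates 1, 2 and 4 against the rest, and the split of replicates 1 and 2 against 3 and 4 called 118, so these arrays hold a structure other than oxygen. At 24 h 1 of 35 splits called as many (7193, highest other 15), which excludes chance only if the arrays are unpaired. Replicate numbers pair the arrays there, and of the 8 splits that part all 4 pairs the highest other called 0. The real split can be no rarer than 1 of these 8, so they cannot exclude chance by themselves. Over time the real split was the 1 of 35 in normoxia (11221, highest other 4) and in hyperoxia (13300, highest other 2), so chance is excluded for these totals. The correlation of the effects at 6 h and 24 h, 0.314, was the highest of 100 draws (1 of 100, highest other 0.266). It was also the highest with the pairs at 24 h kept (1 of 100, highest other 0.260). Only 4 and 13 of these draws, the real one included, had the real grouping at 24 h. Too few regroupings of 6 h thus stood against the real 24 h effect, and chance is not excluded for the part that rests on 6 h. For the number of lists passing camera chance is not excluded either: 10 of 35 splits gave as many at 6 h (11, highest other 15) and 14 of 35 at 24 h (12, highest other 17). With an estimated correlation 2 of 35 splits gave as many at 6 h (1, highest other 2), so chance is not excluded there. At 24 h it was 1 of 35 (7, highest other 1), but these 35 splits do not keep the pairs. None of these counts can part oxygen from slide row, or time from slide.

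The p53 targets rose at 6 h and more at 24 h. At 6 h the real split was the 1 of 35 with as many members called in 1 direction (16, highest other 1). Most other splits called no gene at all, so few could have reached as many. In addition, 7 of 8 arrays at 6 h correlated best with their own number. Chance is thus excluded for 6 h only if these arrays are unpaired. The list was picked out of 33, but in no other split did any list reach as many (1 of 35 splits, highest other 3). A bias between slide rows that depends on brightness is argued against, since the list medians of 0.52 and 1.46 lay at percentile 100 of random lists matched on mean signal at each time (these reached from -0.04 to 0.04 and from -0.10 to 0.11). A changed share of another cell type with a marker list would need its markers to move about as far at 24 h. The median farthest from 0 among those lists was 0.34 (SD of members 0.59). Cell types without a list, such as mast cells, and the share of type II cells were not covered. Activation of p53 by hyperoxia remains a hypothesis, and a bias between slide rows of another kind, found and tested on the same arrays, stays open.

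Genes of mitosis fell at 24 h, with a list median of -2.28. Against a brightness bias between slide rows, that median lay at percentile 0 of matched random lists (-0.11 to 0.13). Against the loss of 1 whole other cell type with a marker list, the lowest median among those lists was -0.081 (SD of members 0.35). Fewer dividing cells of any type under hyperoxia may account for the fall, and neither a loss of a dividing subset nor an arrest within cells was tested.

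The HIF and glycolysis list shifted up at 6 h, although oxygen was raised. For this list the real split had the smallest camera p (1 of 35 splits, 1.06e-11 against 3.55e-11 for the nearest other). The list was picked out of 33, however, and in 15 of 35 splits some list had a p as small (smallest other 4.24e-26), so chance is not excluded. The list median of 0.15 lay at percentile 100 of matched random lists (-0.02 to 0.04), which argues against a brightness bias. With the preset correlation limma's camera gave p = 8.17e-12 over its 31 members in no other list, and the highest camera p with an array left out was 2.41e-08. Since camera gave this list a p of 3.55e-11 under another split, these p-values cannot exclude shared members or a single array. The list median stayed at 0.13 to 0.19 with any 1 array left out, so no single array made up that median. With an estimated correlation its adjusted p was 0.0658, and at 24 h members went both ways, so chance and a difference between slide rows stay open for this shift.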

How the results depend on the processing

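The replicate block within a slide, leaving out the dimmest array, the RefSeq symbols and the HIF list without shared members were chosen after the data were seen. Counts of genes stayed within 1.5 times, and the correlation of 0.314 within its error, except as follows. At 6 h, counts higher were 21 with only the arrays compared, 303 with array weights and 17 at a fold of at least 2, and counts lower were 39 under quantile normalization, 39 under normexp, 37 with the authors' table, 8 with only the arrays compared, 36 with trend and robust moderation, 262 with array weights and 3 at a fold of at least 2. A fold of at least 2 left 668 higher and 517 lower at 24 h, 476 and 1694 over time in normoxia, 833 and 1906 in hyperoxia and 366 and 379 in the difference. Median scaling gave 10103 and 3410 over time in normoxia and 10679 and 4204 in hyperoxia, normexp 8465 and 3649, with 4614 lower in hyperoxia, and RefSeq symbols alone 4603 lower in hyperoxia, fewer genes being counted. Array weights gave 3137 and 2603 in the difference. With an estimated correlation 1 list passed at 6 h and 7 at 24 h. A minimum fold and counting RefSeq symbols alone lower counts by construction, and otherwise the cause was not tested.

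With 1 array left out the counts were 33 to 132 higher and 11 to 61 lower at 6 h, 3306 to 3593 and 2728 to 3065 at 24 h, 4329 to 4805 and 5047 to 5638 over time in normoxia, 5569 to 6757 and 6150 to 6925 in hyperoxia, and 1291 to 2707 and 1159 to 2265 in the difference. The correlation was 0.223 to 0.33, and 9 to 13 lists passed at 6 h and 11 to 13 at 24 h. The transitional list at 6 h turned to a median of -0.020 without hyperoxia 6 h replicate 3 (adjusted p = 0.203), and reached 0.13 at most with another array left out. Without the dimmest array 3390 genes rose and 3065 fell at 24 h. With replicates as a block 63 rose and 18 fell at 6 h and 4086 and 3395 at 24 h, and within slides 66 and 28, and 4718 and 3761. At 6 h the block ended the call of Depdc1b (adjusted p = 0.0588), and within slides those of Bub1b (0.0558) and Kbtbd12 (0.0715). Within slides the type I (adjusted p = 0.000548), type II (0.0123), inflammatory (0.0211) and macrophage lists (0.0301) passed at 6 h, each at 0.822 with an estimated correlation and no block. At 6 h same-numbered arrays correlated at 0.25, 0.25, 0.35 and 0.09. Of the named genes' values under alternatives 762 kept direction and side of the threshold at 6 h, 54 lost and 1, Cd4, gained a call, and 1481 kept and 68 lost it at 24 h. For the lists 178 kept, 19 lost and 1 reversed at 6 h, and 218 kept and 10 lost at 24 h. Slide as a block was not run, since each slide holds 1 time. Signal over background limits genes that were well above it on few arrays, whose folds normexp lowered: Kbtbd12 at 6 h from 2.03 to 0.65 and Cxcl15 at 24 h to 0.03.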

Other observations

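The tests of histone and Hox genes, with the splits for the histone set, were chosen after members of both families were seen among the largest changes.

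The linker histone genes H1f1 and H1f5 were among the falls at 6 h. Of 44 tested genes of the replication-dependent histone clusters 4 fell at 6 h and 0 rose, H1f5, H1f1, H2ac22 (-0.57) and H2ac11 (-0.54), and the median log2 fold change was -0.18, downward under every scaling tried. Since H1f1 and H1f5 had drawn attention to the family, it was tested without them. The other 42 were lower than other genes by limma's camera (p = 3.17e-12, median -0.18, and p = 0.0365 with an estimated correlation), and 2 of them fell by themselves. The real split gave the smallest p of that set (1 of 35 splits, 7.72e-07 for the nearest other). The family was picked for its members, however, and in 15 of 35 splits some fixed list had a p as small as that of this set (smallest other 4.24e-26). A downward shift of the family at 6 h may thus be present, but is not shown for the family as a whole. At 24 h the family was split, with 12 of 44 higher and 22 lower (median -0.31, camera p = 0.00439, and p = 0.365 with an estimated correlation). Without H1f1 and H1f5 the median at 24 h was -0.12 (camera p = 0.0296, and p = 0.477 with an estimated correlation).

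Hoxc13 was among the largest rises at 24 h, and the hypothesis that Hox genes rose as a set was tested. Of 22 tested Hox genes 6 rose and 1 fell, with a median of 0.18 and camera p = 0.0219 (p = 0.263 with an estimated correlation), upward under every scaling tried. Without Hoxc13 and Hoxc9, which had been seen first, the set did not pass limma's camera with the preset correlation (p = 0.124, median 0.10 over 20 genes). Of these 20 genes 4 rose and 1 fell. At 6 h the family lay the other way (median -0.11 over 22 genes, camera p = 0.0167, and p = 0.244 with an estimated correlation), downward under every scaling tried, with 0 members called. No rise of the family as a set is shown.

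Besides the mast cell protease genes Mcpt1 and Mcpt2, named in the comparison of times, Mcpt4 was higher by 1.58 ± 0.32 in normoxia and 2.71 ± 0.32 in hyperoxia, and by 1.18 ± 0.32 in hyperoxia against normoxia at 24 h (limma adjusted p = 0.0121). The mast cell tryptase gene Tpsb2 changed by -0.32 ± 0.12 in normoxia and -0.30 ± 0.12 in hyperoxia over the same times. These genes were chosen after their values were seen.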
